A study of Mus musculus with 4 samples.

How the data were processed

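RNA from EpCAM-positive lung cells of E18.5 mouse embryos was measured by RNA sequencing in 4 libraries, 2 of conditional Emc3 knockout embryos and 2 of wild-type embryos. Per the labels, RNA was isolated with an RNeasy Micro kit and libraries were made with the Nextera XT kit. The submitters' processing notes name Bowtie2 2.1.0, TopHat2 2.0.8, Cufflinks 2.0.2 and DESeq (version not given) with the mm10 genome, without saying what each was used for. The annotation and any filter on reads are not given in the sources used here.

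The deposited table holds 23444 genes with 1 column per library in RPKM, the authors' unit per the file headers, not log transformed. It also holds the authors' p-value per gene, not marked as adjusted, and the authors' signed fold change (a score that is the ratio where it is at least 1 and minus its inverse where it is lower), per the file headers. That the columns are RPKM was taken from the headers of the authors' filter columns and checked on the values: the authors' filter on RPKM above 2 was true for exactly the genes above 2 in any of the 4 columns. Whether the values are RPKM or the closely related FPKM that Cufflinks reports is not given. The authors' p-values and fold changes were used only where a sentence names them as the authors' deposited table.

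Libraries were grouped by the column headings, mutant or control. The sample titles put 2 of the 4 numbered libraries in the opposite group, and a setting added after the data were seen repeats the tests with the groups of the titles. The headings were read first and the Emc3 values next, and the assignment of columns to groups was written down after both. It rests on the headings, but it was not made without knowledge of Emc3. Libraries are called KO 27, KO 35, WT 27 and WT 35 by heading and by the first number in it.

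The plan had 1 test for counts and 1 for normalized values, and since the table holds RPKM the second was used. Genes with at least 1 RPKM in at least 2 libraries were kept (10128; 5819 genes were at 0 in all 4 libraries). Differences were tested on log2(RPKM + 1) with limma 3.58.1 in R 4.3.3, with a trend in the prior variance and genotype as the only term, which leaves 2 residual degrees of freedom and 3.65 prior degrees of freedom. P-values are two-sided and Benjamini-Hochberg adjusted over all tested genes, with a threshold of 0.05. Log2 fold changes are KO minus WT on the log2(RPKM + 1) scale, so for genes of low RPKM they are smaller than the log2 of the RPKM ratio.

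Gene lists were tested with camera at a preset correlation of 0.01 between genes where at least 5 members were tested, with p-values adjusted over the lists, and again with the correlation estimated for each list and with fry. Members were also adjusted over the list alone. The 28 lists, the tests, the other settings and the rule for named genes were fixed before the data were examined. The rule names Emc3, up to 10 genes in each direction with the largest fitted change among those past the threshold with groups that do not overlap and a mean of at least 5 RPKM, up to 4 members of each list with the smallest p, the 4 surfactant protein genes, and Hspa5, Ddit3, Xbp1, Ager, Hopx and Foxj1. Results of 1 gene are not reported here, and of the other genes that the rule names the text gives a selection. Other genes are named with the statement that they were chosen after their values were seen.

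The other settings were quantile normalization, limma without the trend, no filter, a filter of 10 RPKM, pseudocounts of 0.1 and 5, and each library left out in turn. Added after the data were seen were a block by the heading numbers 27 and 35, the groups of the titles, the other remaining split of the 4 libraries, and the exclusion of microRNA and small nucleolar RNA genes. The planned tests for counts could not be run on RPKM, and the planned block by the replicate numbers of the titles could not be fitted. The test was tried on simulated data of the same size, with 200 of 10128 genes changed: it recovered 0 of 200 at a log2 change of 1, 157 at 2 with 6 false calls, and 182 at 3 with 2 false calls. The changed genes were drawn only from those whose mean log2(RPKM + 1) was above that of 5 RPKM. With camera, 100 of 100 simulated lists of 16 genes shifted by 0.5 were called, and 7 of 100 unshifted lists. The simulated genes were uncorrelated, so this says nothing about lists of correlated genes.

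Gene positions are from the RefSeq annotation of GRCm38, matched by symbol for 21890 of 23444 symbols. The number of reads per library is not given, so precision is given only as the spread between libraries. Figures and the comparison with the deposited fold changes used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Raw reads were not used here.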

Results

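RNA was sequenced from EpCAM-positive cells sorted from the lungs of mouse embryos at E18.5 (days of gestation), close to birth, when the distal epithelium holds maturing alveolar type 2 (AT2) cells, which make surfactant, and the flat alveolar type 1 (AT1) cells. EpCAM is a surface protein of epithelial cells. The embryos were wild-type (WT, 2 libraries) or carried a conditional knockout of Emc3 in the developing lung epithelium (KO, 2 libraries). EMC3 is a core subunit of the endoplasmic reticulum (ER) membrane protein complex, which helps to insert many membrane proteins into the ER membrane. The values are the authors' RPKM (reads per kilobase of gene, scaled to the mapped reads of the library) for 23444 genes, and errors after ± are SD with n = 2 per group. Libraries are named by group and by the first number in their column heading, 27 or 35, whose meaning is not given in the sources used here.

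The deposited labels do not give 1 grouping. The RPKM columns are headed mutant for KO 27 and KO 35 and control for WT 27 and WT 35, whereas the sample titles with the same numbers call KO 27 wild-type and WT 35 knockout. All directions below follow the column headings. Each group held 1 male and 1 female library by Xist and Eif2s3y, so the libraries of a group come from different animals. The labels do not tell whether a library comes from 1 animal or several, or from which litter, and the p-values measure only the spread between these samples. Genotype by heading is the only grouping of the 4 libraries in which Emc3 differs by more than 1 log2 unit.

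RPKM summed to 141373 in KO 27, 146918 in KO 35, 151616 in WT 27 and 169294 in WT 35, and between 9815 and 9964 genes per library reached 1 RPKM. The lowest RPKM steps put the relative depths of the libraries within a ratio of 1.10, while the absolute depth is unknown, so no counting interval or detection limit is given. The 10 most abundant genes took 14.1% and 15.4% of the total in KO 27 and KO 35, and 20.5% and 26.5% in WT 27 and WT 35. A larger share in 10 genes leaves a smaller share for all others, but the RPKM totals were also larger in WT. These shares therefore do not show that the other genes were placed lower in WT than in KO. Scgb1a1, named after its values were seen, accounted for 9678 RPKM in WT 35 and for 1559.6 to 2698 RPKM in the other libraries. On log2(RPKM + 1) over 10128 genes, the correlation across genes was 0.965 between the KO libraries, 0.949 between the WT libraries and 0.934 to 0.946 across the groups. The first principal component held 48.0% of the variance and separated KO from WT.

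Emc3 fell in KO. It was at 2.28 RPKM in KO 27 and 2.33 in KO 35, against 14.2 in WT 27 and 18 in WT 35, which is 2.30 ± 0.0350 against 16.1 ± 2.66 RPKM and a 6.99-fold lower mean. Emc3 lies on chromosome 6 from 113514887 to 113531638 (GRCm38, the build that the authors' mm10 names). On the log2(RPKM + 1) scale the difference was -2.36 (SE 0.16, limma adjusted p = 0.0242), with both KO libraries below both WT libraries. The call ended without KO 27 (adjusted p = 0.0664) and without KO 35 (adjusted p = 0.0642), where the remaining KO library is assumed to vary like the WT libraries, and with a filter of 10 RPKM (adjusted p = 0.0696) or no filter (adjusted p = 0.278). Over all settings that keep the groups of the headings the log2 difference lay between -2.74 and -1.53 and the adjusted p between 0.00963 and 0.278.

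Which other genes differed between KO and WT was asked next. Thbs1 and Anxa5 rose in KO. Thbs1 encodes the secreted matrix protein thrombospondin 1 (chromosome 2, 118111876 to 118127133) and was at 41.0 ± 3.58 RPKM in KO and 6.66 ± 0.185 in WT, a log2 fold change of 2.45 (SE 0.14, adjusted p = 0.0125). Anxa5 encodes annexin A5, a calcium-dependent phospholipid-binding protein (chromosome 3, 36448923 to 36475887), and was at 31.3 ± 2.43 RPKM in KO and 9.01 ± 0.133 in WT, a log2 fold change of 1.69 (SE 0.14, adjusted p = 0.0442). With Emc3 these were the protein-coding genes among the 7 of 10128 genes past an adjusted p of 0.05 (3 higher, 4 lower, all by at least 2-fold on the fitted scale). Anxa5 lost its call when either KO library was left out (adjusted p = 0.102 and 0.152), under 4 of the other settings (adjusted p from 0.0510 to 0.278), and when microRNA and small nucleolar RNA genes were not tested (adjusted p = 0.0626), its lowest adjusted p under any setting being 0.0261. Among the settings that keep the groups of the headings, Thbs1 lost its call only with no filter (adjusted p = 0.103, range from 0.00733).

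The other 4 calls were small RNA genes listed at 0 in both libraries of 1 group. Snord22 (chromosome 19, 8725866 to 8725991) was at 35 and 31.2 RPKM in KO 27 and KO 35 and listed at 0 in WT. Mir431 (chromosome 12, 109590447 to 109590537) was at 165 and 115 RPKM in WT 27 and WT 35, Mir370 (chromosome 12, 109618258 to 109618336) at 7751 and 1038, and Snora31 (chromosome 14, 75847923 to 75848034) at 56.8 and 20.8, all 3 being listed at 0 in KO. Each lies by position inside a longer gene, and none of these surrounding genes passed the test. Strand was not compared, so a surrounding gene need not be the one that the small RNA is transcribed with. Snhg1, around Snord22, was at 49.5 ± 7.41 RPKM in KO and 30.5 ± 2.15 in WT (log2 fold change 0.68) and Rtl1, around Mir431, at 24.7 ± 2.66 and 29.2 ± 3.49 (log2 fold change -0.23). Rian, around Mir370, was at 121.3 ± 9.89 and 121.4 ± 25.9 RPKM, and Tpt1, around Snora31, at 712 ± 64.8 and 647 ± 197. The surrounding genes were looked up after the calls were seen. Among the settings that keep the groups of the headings, Mir431 kept its call in all, Snord22 lost it with a filter of 10 RPKM (adjusted p = 0.0531), Mir370 in 4 settings (adjusted p from 0.0590 to 0.387) and Snora31 in 8 (adjusted p from 0.0507 to 0.387). A small RNA gene and the gene around it overlap in position and the library kit does not mark strand, so their reads cannot be told apart. No fold is given for these genes.

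**Figure D1:**
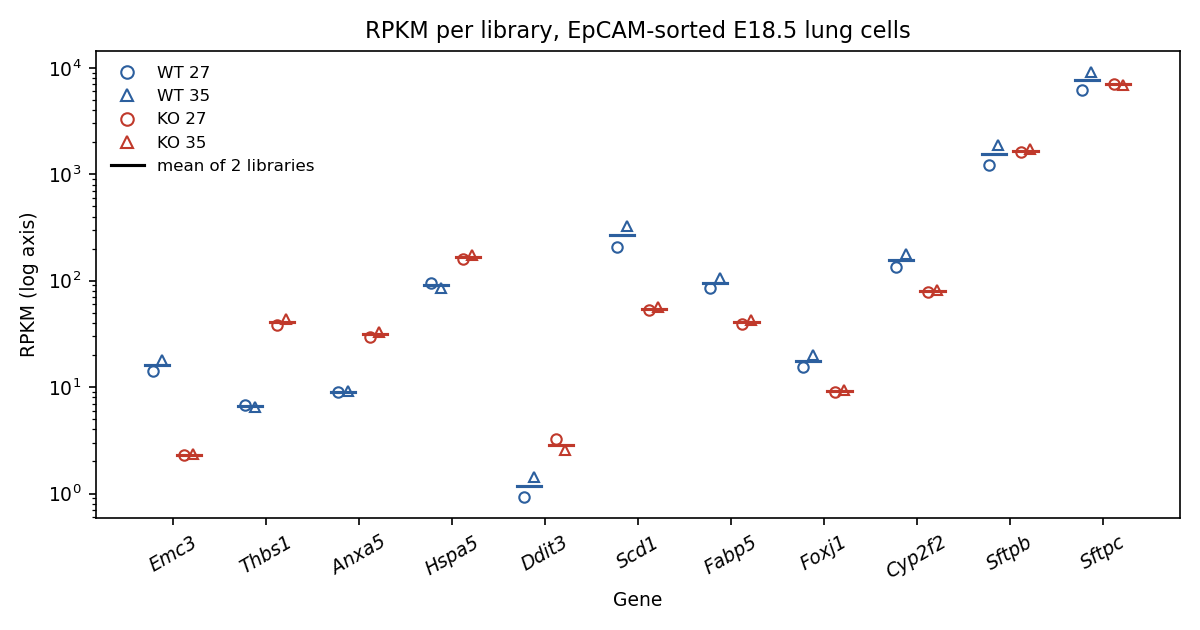
RPKM on a log axis for 11 named genes, with 1 symbol per library (circles 27, triangles 35), WT in blue, KO in red, and bars at the mean of the 2 libraries. Emc3 is at 2.28 and 2.33 RPKM in KO against 14.2 and 18 in WT, Thbs1, Anxa5, Hspa5 and Ddit3 lie higher in both KO libraries, Scd1, Fabp5, Foxj1 and Cyp2f2 lie lower, and the WT values of Sftpb and Sftpc lie on both sides of the KO values.

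Beyond these calls, 1402 genes had an unadjusted limma p under 0.05 (827 higher, 575 lower), where 506.4 would be expected by chance. Both KO libraries lay on the same side of both WT libraries for 46.4% of genes, against 33.3% by chance. The fixed gene lists were therefore tested as sets with camera, which compares the members with all other genes. These leaned higher in KO: KO lay above WT in every library for 3043 genes and below for 1654. The median log2 fold change of all tested genes was 0.056, and 0.015 with quantile normalization. List medians are to be read against this background and not against 0. Of 28 lists 21 had at least 5 tested members, and 10 passed an adjusted p of 0.05 with a preset correlation of 0.01 between members (4 higher, 6 lower). None passed with the correlation estimated from these 4 libraries, the lowest adjusted p being 0.483. With an estimated correlation camera has only the 2 residual degrees of freedom. Even the ER chaperones, with all 16 members higher, had an unadjusted camera p of 0.0230 there. A list that did not pass this test is therefore not shown to be unchanged. Fry, which asks whether a list moves at all, called 1 list (5 in either direction). Camera at the preset correlation also gave low adjusted p-values for other groupings of the libraries. Examples are 4.33e-08 for the cell cycle list with the groups of the titles, and 2.11e-07 for AT1 markers with the split by sex. The groups of the titles put the libraries of heading number 27 against those of 35. Real differences by heading number or by sex were not excluded, so these groupings cannot show how often such p-values arise without a difference. With that rate unknown, a camera p of this size at the preset correlation does not by itself show a difference by genotype. In simulated data of this size limma recovered 0 of 200 genes changed by 1 log2 unit and 157 of 200 changed by 2. Single members of like level with smaller differences were therefore not expected to pass. The changed genes were drawn only from those with a mean level above that of 5 RPKM, so recovery at lower levels is not known.

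Genes of protein folding in the ER were higher in KO as groups. All 16 tested ER chaperones and folding enzymes had positive log2 fold changes, with a median of 0.52, and 15 of them had both KO libraries above both WT libraries. Hspa5, which encodes BiP, the main chaperone of the ER lumen (chromosome 2, 34772090 to 34776529), was at 165 ± 10.5 RPKM in KO and 90.1 ± 7.45 in WT (log2 fold change 0.87, adjusted p = 0.159). Manf, which encodes a secreted protein of the ER stress response, was at 4.15 ± 0.177 and 2.20 ± 0.147 RPKM, calreticulin (Calr) at 43.1 ± 1.61 and 27.8 ± 2.30, and the disulfide isomerase Pdia4 at 22.4 ± 0.584 and 14.1 ± 1.83. No member passed the test over all genes, and 13 passed adjusted over the list alone. The list passed camera (adjusted p = 1.65e-08), which was lost with an estimated correlation (adjusted p = 0.483 with an estimated correlation), and it was the 1 list called by fry (adjusted p = 0.0157).

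The genes of ER-associated degradation and other targets of XBP1, a transcription factor of the unfolded protein response, had positive log2 fold changes for 18 of 18 tested members, with a median of 0.38. The disulfide isomerase Pdia5 was at 5.60 ± 0.974 RPKM in KO and 2.78 ± 0.261 in WT, the co-chaperone Dnajb9 at 10.6 ± 3.10 and 4.63 ± 1.47, Serp1 at 38.6 ± 3.87 and 25.1 ± 2.35, and the ubiquitin ligase Syvn1 at 15.4 ± 2.1 and 9.70 ± 1.21. Xbp1 itself was at 22.2 ± 6.05 and 14.6 ± 2.56 RPKM. None passed over all genes, 4 passed adjusted over the list alone, and the list passed camera (adjusted p = 1.16e-05; adjusted p = 0.483 with an estimated correlation). With a pseudocount of 5 the median was 0.22.

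Targets of ATF4 and CHOP, transcription factors of the integrated stress response, had a median log2 fold change of 0.43, with 18 of 22 members positive. Atf5 was at 6.63 ± 3.02 RPKM in KO and 1.64 ± 0.447 in WT, the mitochondrial folate enzyme Mthfd2 at 1.87 ± 0.911 and 0.20 ± 0.136, and Ddit3, which encodes CHOP, at 2.88 ± 0.480 and 1.18 ± 0.359. Cth, which makes cysteine from cystathionine, went the other way at 0.591 ± 0.0414 and 1.98 ± 0.626 RPKM. Mthfd2 was below 1 RPKM in both WT libraries and Cth in both KO libraries. The filter therefore kept each of them only because of its level in the other group. No member passed over all genes, and 8 higher and 1 lower passed adjusted over the list alone. The list passed camera (adjusted p = 0.00298; adjusted p = 0.556 with an estimated correlation), and not with a filter of 10 RPKM (adjusted p = 0.317, range from 1.14e-05). Without KO 35 the median was 0.23, and with a pseudocount of 5 it was 0.21.

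Other factors of ER membrane insertion and translocation were higher as a group by a smaller margin, with a median of 0.20 and 16 of 20 members positive. Sec61b, a subunit of the translocon channel, was at 40.6 ± 5.72 RPKM in KO and 21.9 ± 4.15 in WT, Tram1 at 19.8 ± 1.46 and 13.3 ± 0.959, and the translocon-associated Ssr4 at 18.7 ± 3.87 and 11.3 ± 0.451. None passed over all genes or adjusted over the list alone, while the list passed camera (adjusted p = 0.00736; adjusted p = 0.550 with an estimated correlation) and not without KO 35 (adjusted p = 0.0502, range from 0.0023; median 0.51 with a filter of 10 RPKM). The EMC subunits passed camera as lower (adjusted p = 0.0218; adjusted p = 0.550 with an estimated correlation; median -0.09), with Emc3 as the 1 member to pass, both over all genes and adjusted over the list alone. Without KO 35 the list did not pass (median -0.04, adjusted p = 0.0543), nor without WT 35 (median -0.01, adjusted p = 0.107), and its median was -0.17 without WT 27 and -0.047 with a pseudocount of 5. For the other 9 subunits, a test chosen after the list was seen gave an unadjusted camera p of 0.111 from limma's fit, with log2 fold changes from -0.48 (Emc9, 1.04 ± 0.756 RPKM in KO and 1.76 ± 0.449 in WT) to 0.03. Beside all of these higher lists, the 4 tested immune cell markers were higher in both KO libraries as well, with list means of 2.09 and 1.79 in KO 27 and KO 35 and 1.07 and 0.859 in WT 27 and WT 35 on the log2(RPKM + 1) scale. Of these markers, Tyrobp and Cd52 passed the filter only through the KO libraries.

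Among surfactant genes no difference passed. Sftpc, the AT2 cell's surfactant protein C gene (chromosome 14, 70520941 to 70524081), was at 6979 ± 188 RPKM in KO and 7645 ± 2092 in WT, Sftpb at 1655 ± 77.2 and 1538 ± 457, Sftpa1 at 513 ± 29.8 and 559.5 ± 231, and Sftpd at 118 ± 26.0 and 93.5 ± 44.8. The spread between WT 27 and WT 35 exceeded the difference between the groups for each of them. Abca3, the lipid transporter of the lamellar bodies that store surfactant, was at 55.4 ± 5.40 RPKM in KO and 80.1 ± 14.0 in WT, and the protease Ctsh at 1030.2 ± 120.1 and 716 ± 164. The surfactant and lamellar body list had a median log2 fold change of -0.08 over 10 members, none of which passed over all genes or adjusted over the list alone, and it did not pass camera (adjusted p = 0.539). Quantile normalization turned this median to 0.20 and the log2 fold change of Sftpc from -0.10 to 0.86, and without WT 27 the list passed as lower (median -0.34, adjusted p = 0.00494, range to 0.758), while without WT 35 its median was 0.18.

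Other AT2 markers were lower as a group, with a median of -0.36 and 12 of 14 members negative. Fabp5, which encodes a fatty acid binding protein, was at 41.1 ± 2.42 RPKM in KO and 95.5 ± 14.5 in WT (log2 fold change -1.19, adjusted p = 0.108). Lyz1, a lysozyme gene, was at 388 and 517 RPKM in KO 27 and KO 35 against 1003 and 3163 in WT 27 and WT 35, and Chil1 at 12.4 and 7.64 against 129 and 27.1. Egfl6 was higher in both KO libraries, at 285 ± 11.2 against 159.9 ± 7.65 RPKM. No member passed over all genes, and 3 lower and 1 higher passed adjusted over the list alone. The list passed camera (adjusted p = 0.00246; adjusted p = 0.550 with an estimated correlation). Without WT 35 the median was -0.02 and the list did not pass (adjusted p = 0.0696, range from 5.78e-06). WT 35 is also the library with the largest share of its RPKM in 10 genes, 26.5%.

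Genes of fatty acid and phospholipid synthesis were lower as a group, with a median of -0.17 and 14 of 21 members negative. Scd1, which encodes the stearoyl-CoA desaturase that makes monounsaturated fatty acids (chromosome 19, 44394450 to 44407709), was at 54.5 ± 2.34 RPKM in KO and 266 ± 84.8 in WT, a log2 fold change of -2.23 (SE 0.24) that did not pass (adjusted p = 0.0670). Its paralogue Scd2 was at 78.0 ± 3.95 and 167 ± 34.9 RPKM, and Srebf1, a transcription factor of lipid synthesis, at 8.56 ± 0.819 and 14.2 ± 1.33, while Pparg, a transcription factor of lipid storage, was at 2.76 ± 0.858 and 1.0 ± 0.0202. Over all genes none passed, and adjusted over the list alone 4 lower and 1 higher did. The list passed camera (adjusted p = 0.00298; adjusted p = 0.483 with an estimated correlation), with a median of -0.33 without WT 27 and -0.09 without WT 35.

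Cholesterol synthesis and uptake had a median of -0.06 with 16 of 22 members negative, led by Hmgcs1 at 6.80 ± 0.530 RPKM in KO and 12.0 ± 0.468 in WT, while Pmvk of the same pathway was at 6.86 ± 0.903 and 4.2 ± 0.837. No member passed over all genes, and 1 lower passed adjusted over the list alone. The list passed camera (adjusted p = 0.0414; adjusted p = 0.483 with an estimated correlation). It lost this call without KO 27 (median -0.12, adjusted p = 0.169), without WT 27 (median -0.12, adjusted p = 0.157), without WT 35 (adjusted p = 0.0504), and under 3 other settings (adjusted p from 0.0515 to 0.0561). The median was -0.14 without KO 35, -0.12 with quantile normalization and -0.30 with a filter of 10 RPKM (adjusted p = 0.00193, the lowest). WT 27 and WT 35, the higher group for these lipid genes, also had the larger shares of RPKM in 10 genes, 20.5% and 26.5% against 14.1% and 15.4% in KO. The RPKM totals of WT 27 and WT 35 were larger as well. The shares therefore do not show a bias for or against the lipid lists or the lists higher in KO. Of the lists higher in KO, the ER chaperones had a median of 0.46 with quantile normalization.

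Markers of ciliated airway cells were lower in KO as a group. All 13 tested members had negative log2 fold changes, with a median of -0.57, and in 11 both KO libraries lay below both WT libraries. Foxj1, the transcription factor of motile cilia (chromosome 11, 116330704 to 116335499), was at 9.13 ± 0.231 RPKM in KO and 17.6 ± 3.21 in WT, Rsph1 of the radial spokes at 8.22 ± 0.601 and 17.8 ± 2.35, Tekt1 of the ciliary microtubules at 3.77 ± 0.566 and 6.98 ± 1.75, and 1700009P17Rik (Cfap126) at 4.86 ± 0.443 and 13.3 ± 5.46. None passed over all genes, 5 passed adjusted over the list alone, and the list passed camera (adjusted p = 1.65e-08; adjusted p = 0.483 with an estimated correlation). The median was -0.96 without WT 27, and -0.39 without WT 35. As for the club cell genes, WT 35 was the library with the highest levels, with list means of 3.12 in WT 27 and 3.64 in WT 35 against 2.73 and 2.76 in KO 27 and KO 35 on the log2(RPKM + 1) scale.

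Markers of club and other secretory airway cells were also lower as a group, with a median of -0.53 and 7 of 8 members negative. The carbonyl reductase gene Cbr2 was at 354 ± 7.13 RPKM in KO and 617 ± 45.0 in WT, the cytochrome P450 gene Cyp2f2 at 80.4 ± 2.62 and 157 ± 31.5, Aldh1a7 at 32.0 ± 0.0187 and 49.5 ± 7.68, and Scgb3a2 at 99.3 ± 12.7 and 138 ± 29.8. No member passed over all genes, and 3 passed adjusted over the list alone. The list passed camera (adjusted p = 0.00194; adjusted p = 0.483 with an estimated correlation), and not with no filter (median -0.26, adjusted p = 0.0633, range from 0.000465). Scgb1a1, the most abundant club cell gene and one named after its values were seen, was at 1559.6 and 2698 RPKM in KO 27 and KO 35 and at 2556 and 9678 in WT 27 and WT 35, the libraries with 20.5% and 26.5% of their RPKM in 10 genes. Of the basal cell markers only Krt15 (3.53 ± 1.37 RPKM in KO, 8.94 ± 3.17 in WT) and Aqp3 (1.44 ± 0.279 and 0.553 ± 0.371) were tested. Of these, 1 lower and 1 higher passed adjusted over the list alone and neither over all genes. Aqp3 was below 1 RPKM in both WT libraries, so the filter kept it only because of its level in KO.

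**Figure D2:**
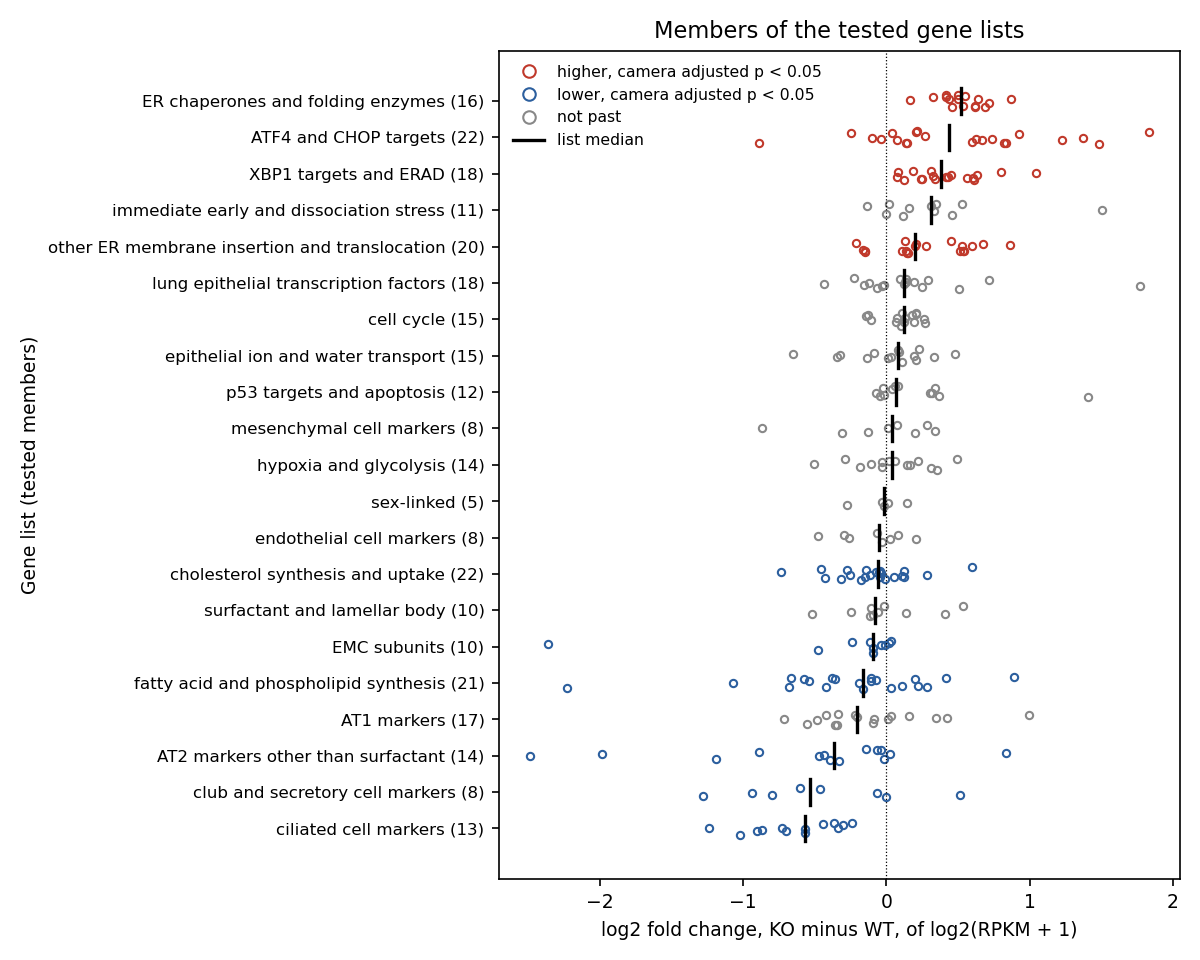
Log2 fold change (KO minus WT, of log2(RPKM + 1)) of each tested member of the 21 tested lists, with the number of members in brackets and a black bar at the list median; red lists were higher and blue lists lower at a camera adjusted p under 0.05 with the preset correlation, none of which held with an estimated correlation. The medians run from -0.57 for ciliated cell markers to 0.52 for ER chaperones and folding enzymes.

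AT1 markers did not pass as a list (median -0.20, adjusted p = 0.0784), and none of 17 members passed over all genes or adjusted over the list alone. Ager was at 54.1 ± 5.84 RPKM in KO and 69.6 ± 16.9 in WT, Hopx at 55.6 ± 0.805 and 68.9 ± 32.4, the caveolin gene Cav1 at 50.3 ± 4.90 and 70.7 ± 2.71, the tight junction gene Cldn18 at 198 ± 4.64 and 148 ± 5.57, and S100a6 at 45.1 ± 21.7 and 21.0 ± 3.30. The list passed as lower without WT 35 (median -0.40, adjusted p = 5.96e-05) and without KO 35 (adjusted p = 0.0153), and its median was 0.10 without WT 27 (adjusted p = 0.736, the highest). Among 18 lung epithelial transcription factors, which did not pass as a list (median 0.13, adjusted p = 0.572), Tfcp2l1 was at 43.5 ± 1.90 RPKM in KO and 12.1 ± 2.39 in WT, a log2 fold change of 1.77 that passed adjusted over the list alone and not over all genes (adjusted p = 0.0670). Ehf was at 3.60 ± 1.09 and 1.77 ± 0.128 RPKM and Etv5 at 65.8 ± 5.43 and 89.2 ± 4.79. The median of this list was 0.015 without WT 27, 0.074 without KO 27, 0.064 with quantile normalization and 0.051 with a filter of 10 RPKM.

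The remaining tested lists of cell state did not pass, and none of their members passed over all genes or adjusted over the list alone. The p53 target and cell cycle inhibitor gene Cdkn1a was at 18.2 ± 4.21 RPKM in KO and 6.51 ± 3.29 in WT, in a list with a median of 0.07 (adjusted p = 0.210) that was 0.19 without KO 27 and 0.20 without WT 35. The cell cycle list had a median of 0.12 (adjusted p = 0.626) and passed as higher without WT 27 (median 0.36, adjusted p = 0.00152), and as lower without WT 35 (median -0.12, adjusted p = 0.0233). Immediate early and dissociation stress genes had a median of 0.31 (adjusted p = 0.234), with Dusp1 at 83.9 ± 1.66 RPKM in KO and 33.4 ± 23.8 in WT, and passed as higher without WT 35 (median 0.74, adjusted p = 0.00442), while the median was 0.049 without WT 27 and 0.17 without KO 35. Ion and water transport genes (median 0.08, adjusted p = 0.823; Scnn1b 1.93 ± 0.160 RPKM in KO and 3.64 ± 0.886 in WT) and genes of hypoxia and glycolysis (median 0.04, adjusted p = 0.877; Pdk1 3.70 ± 0.196 and 5.66 ± 0.0971) had test directions opposite to their medians. Of the interferon response and inflammatory mediator lists 3 members each were tested, too few for camera, and none passed. Median and mean differed in sign for inflammatory mediators (-0.16 and 0.0005).

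Markers of cells that the EpCAM sort should remove were present at different levels. The mesothelial gene Msln was at 12.3 to 21.6 RPKM over the 4 libraries, with overlapping groups. The mesenchymal gene Col1a1 was at 5.15 ± 0.114 RPKM in KO and 6.73 ± 1.67 in WT, Mfap4 at 5.91 ± 1.17 and 11.6 ± 1.68, the endothelial gene Kdr at 1.76 ± 0.209 and 2.84 ± 0.448, and the globin gene Hba-a1 at 1.53 ± 0.343 and 2.77 ± 1.5. Neither the mesenchymal list (median 0.04, mean -0.05, test direction lower, adjusted p = 0.591) nor the endothelial list (median -0.05, adjusted p = 0.175) passed, except that the endothelial list passed as lower without KO 35 (median -0.16, adjusted p = 0.0341, range to 0.764). Mfap4 passed adjusted over the list alone, and no endothelial, erythroid or mesothelial gene did. The 3 mesothelial genes had a median of 0.08 and a mean of -0.04. The 4 immune cell markers that could be tested, of 12, were higher in both KO libraries: Fcer1g was at 8.36 ± 0.690 RPKM in KO and 2.55 ± 0.536 in WT, Tyrobp at 2.68 ± 1.25 and 0.506 ± 0.459, Laptm5 at 2.08 ± 0.726 and 1.04 ± 0.0537, and Cd52 at 1.12 ± 0.161 and 0.377 ± 0.0888. All 4 passed adjusted over the list alone and none over all genes (adjusted p = 0.0689 for Fcer1g), and 4 members were too few for camera. Tyrobp and Cd52 were below 1 RPKM in both WT libraries, so the filter kept them only because of their level in KO. That all 4 tested markers were higher is therefore partly set by the filter. The other 8 were below 1 RPKM in every library, and the order here was chosen after their values were seen: Ptprc and Emr1 were higher in both KO libraries, Csf1r, Cx3cr1, Coro1a, C1qb and C1qc overlapped between the groups, and C1qa was listed at 0 in all. No neuroendocrine marker was abundant enough to be tested.

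Sex was balanced across genotype. Xist was at 55.8 RPKM in KO 35 and 83.8 in WT 27, with 0.135 and 0.114 in KO 27 and WT 35, and the Y-linked gene Eif2s3y was at 8.21 RPKM in KO 27 and 8.57 in WT 35 and listed at 0 in KO 35 and WT 27. With 1 male and 1 female library per group, differences by sex largely cancel in the sex-linked list (median -0.02, adjusted p = 0.754), so its test says nothing about a difference between the genotypes.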

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

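For the deposited fold changes and for the sample titles all tests below were chosen only after the result was seen, and for the ciliated cell genes this holds for the test of dissociation stress and for the choice of the pattern itself.

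A signal appeared in columns of the authors' deposited table that the comparisons above do not use. Among the 6848 genes above 2 RPKM in every library, of which 3476 were placed before and 2980 after a point on chromosome 2 in the order of chromosome names, the log2 fold change of the authors' deposited table lay more than 0.6 below the log2 ratio of the RPKM means for 99.5% of genes after it (2965) and for 8 genes before it (limit chosen after the data were seen). The point lies between gene starts at 147012755 and 148042877, and the part after it holds the rest of chromosome 2, chromosomes 3 to 9 and X. The median difference was -1.04 after the point and -0.06 before it. Among the 496 genes after the point with a p-value under 0.05 in the authors' deposited table, 471 were lower and 0 higher, against 32 lower and 42 higher among 78 before it. Sftpb, after the point, had a fold change of -2.04 in the authors' deposited table, where its RPKM ratio of KO to WT was 1.08, and Emc3 had -13.6 where its RPKM was 6.99-fold lower.

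Of the explanations tested for this shift, lower expression along those chromosomes in KO is argued against by the RPKM, whose median log2 ratio after the point differed by -0.020 from that before it. A candidate explanation is that reads of KO 27 were absent after the point from the counts behind the authors' deposited table: 0.5 times the RPKM of KO 35 over the WT mean followed the deposited values with an SD of 0.122 over genes. Leaving out KO 35 in place of KO 27 gave an SD of 0.302 (95% bootstrap interval of the difference 0.156 to 0.206), which argues against that variant, while 0.5 times the mean of both KO libraries gave 0.178 (interval of the difference 0.0442 to 0.0723), and the SD before the point was 0.0796. The Y-linked genes, seen in KO 27 at 3.24 RPKM for Ddx3y and listed at 0 in KO 35, were marked absent in place of a fold change in the authors' deposited table, which goes with the same candidate. How the authors computed the fold changes is not given, so it stays a hypothesis.

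The genotype in the sample titles differs from the column heading for 2 of the 4 libraries. Grouped by the titles, Emc3 differed by a log2 of 0.17, which may mean that the titles of 2 samples were exchanged. Exchanged headings are argued against, because the library headed control and titled knockout had 7.89 times the Emc3 RPKM of the one headed mutant and titled wild-type. Emc3 had been seen before these tests were written. Whether other labels were exchanged with them stays open.

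Ciliated cell markers were lower in KO, and the fixed list was followed by a list of other motile cilia genes whose values had not been looked at. All 17 tested genes of this list had negative log2 fold changes (median -0.60, SD 0.13, camera p = 5.06e-12, p = 0.144 with an estimated correlation), and its median differed by -0.035 from that of the fixed list, so fewer ciliated cells in the KO sort may account for the pattern, while lower expression per cell stays open. Of 2 genes chosen after their values were seen, Dnah9 differed mainly through WT 35. It was at 2.56 and 5.16 RPKM in WT 27 and WT 35, against 2.28 and 2.42 in KO 27 and KO 35. Dnaaf3 did not, at 1.52 and 1.39 RPKM in WT 27 and WT 35 against 0.666 and 0.292 in KO 27 and KO 35. It was below 1 RPKM in both KO libraries, so the filter kept Dnaaf3 only because of its level in both WT libraries. The median of this list with 1 library left out was not computed. A single library as the cause is argued against, since the median of the fixed list was at most -0.39 whichever library was left out (-0.96 to -0.39). Different dissociation stress cannot be told apart with 2 libraries per group: the immediate early list had an adjusted p of 0.234, which excludes nothing.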

How the results depend on the processing

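The block by heading number, the groups of the titles, the third split of the 4 libraries and the exclusion of small RNA genes were chosen after the data were seen, and the other settings were planned. Tests and scalings that apply to counts only (DESeq2 size factors, the DESeq2 Wald test, limma-voom and edgeR) were not run, since the table holds RPKM. The planned block by the replicate numbers of the titles could not be fitted because these numbers coincide with the genotype of the headings. With both groups of 2, a left-out library leaves 1 library that is assumed to vary like the other group. The cause of a change was not tested except where stated.

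The direction of Emc3 was the same under every setting that keeps the groups of the headings, with adjusted p from 0.00963 to 0.278. No filter tested 17625 genes and a filter of 10 RPKM 2416, in place of 10128. With no filter 2 genes passed (1 higher, 1 lower, both by at least 2-fold) and Emc3, at -2.36, did not; the median of the mesenchymal list was -0.027. With a filter of 10 RPKM 4 genes passed, all 4 by at least 2-fold and 2 of them lower, and Emc3, at -2.36, did not. With a pseudocount of 5, 4 genes passed, all 4 by at least 2-fold and 2 lower. With the block 6 genes were higher. The correlation of deviations from the group means between libraries with the same heading number was 0.148. With 2 libraries per group the deviations are mirror images, so the 2 pairs give the same value by construction. Without microRNA and small nucleolar RNA genes 2 genes passed (1 higher, 1 lower, both at least 2-fold), since these classes supplied 4 of the 7 calls and Anxa5 did not pass (adjusted p = 0.0626, from 0.0261 to 0.278 over the settings that keep the groups of the headings). Quantile normalization, limma without the trend and a pseudocount of 0.1 left the counts within 1.5 times those reported (6, 5 and 10 genes).

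The groups of the titles put the libraries of heading number 27 against those of 35. They gave 4 genes, all 4 small RNA genes changed by at least 2-fold and 2 of them lower, an Emc3 difference of 0.17, and 3 lists past the threshold. The third split, which separates the sexes, gave 6 higher genes among 10 and 6 lists, none of the 10 being among the 7 reported. The sex-linked list is called by the construction of that split, which leaves 5. With an estimated correlation 0 lists passed, and with fry 1.

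Quantile normalization turned Slc34a2 to 0.24, Sftpa1 to 0.16, Sftpc to 0.86 and the medians of the surfactant list to 0.20, of the mesenchymal list to -0.0088 and of the hypoxia list to -0.033. The other 18 list medians and 107 named genes kept their direction and their side of the threshold.

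With 1 library left out at a time, 8 to 43 genes passed (8 to 43 by at least 2-fold, 5 to 16 higher and 2 to 31 lower), and 7 of the 7 reported genes were among the 43 without WT 27 and the 28 without WT 35, against 3 without KO 27 or KO 35. Emc3 ranged from -2.52 to -2.20. Without WT 27, 5 further named genes and 2 further lists passed, without WT 35 4 and 3 (cell cycle with its direction turned), and without KO 35 2 lists. The number of reads per library is unknown, so what depth limits could not be worked out. Log2 fold changes that turned sign ranged from -0.55 to 0.065 for Emc6, -0.10 to 0.91 for Sftpd, -0.55 to 0.053 for Slc34a2, -0.49 to 0.37 for Sftpa1, -0.17 to 0.44 for Sftpb, -0.39 to 0.18 for Sftpc and -0.71 to 0.27 for Hopx. Among markers of other cells they ranged from -0.051 to 0.46 for Egfl7, -0.59 to 0.28 for Hbb-bt, -0.66 to 0.063 for Msln, -0.026 to 0.23 for Lrrn4 and -0.033 to 0.19 for Upk3b. Among genes of cell state they ranged from -0.041 to 0.58 for Kif11, -0.010 to 0.64 for Hspb1, -0.38 to 0.17 for Bst2, -0.39 to 0.28 for Usp18, -0.63 to 0.30 for Lcn2 and -1.03 to 0.71 for Saa3. Sex-linked genes, whose balance a left-out library breaks, ranged from -1.05 to 1.35 for Kdm5d, -3.40 to 2.85 for Xist, -0.79 to 0.76 for Uty and -1.66 to 1.6 for Eif2s3y. List medians that turned sign ranged from -0.34 to 0.18 for surfactant, -0.40 to 0.10 for AT1 markers, -0.12 to 0.22 for mesenchymal, -0.16 to 0.036 for endothelial, -0.12 to 0.36 for cell cycle, -0.070 to 0.16 for ion transport, -0.031 to 0.11 for hypoxia and -1.03 to 1.05 for sex-linked genes.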

Other observations

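The tests of liver X receptor targets and of the alveolar transitional state were chosen only after some of their best known genes had been seen to differ, and the genes named in the first paragraph, as well as Ereg, Anxa1, Clu, Sfn and Itgb6, were chosen after their values were seen.

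Several abundant genes lay far apart between KO and WT without passing the test. Areg, which encodes the growth factor amphiregulin, was at 86.3 ± 28.3 RPKM in KO and 6.86 ± 3.29 in WT (SD, n = 2; limma adjusted p = 0.0670), the hyaluronan receptor gene Cd44 at 20.7 ± 1.52 and 4.53 ± 1.15 (adjusted p = 0.0648), and S100a1, a calcium-binding protein gene, at 31.3 ± 6.56 and 6.80 ± 1.6 (adjusted p = 0.0670). Sprr1a, a cornified envelope protein gene, was at 62.0 ± 46.6 and 0.947 ± 0.456 RPKM. In the other direction, Abca1, which exports cholesterol from cells, was at 1.36 ± 0.136 RPKM in KO and 6.51 ± 0.680 in WT (adjusted p = 0.0502), Gif at 3.86 ± 0.940 and 22.3 ± 7.02, and the lipoprotein lipase gene Lpl at 3.30 ± 0.0316 and 7.86 ± 2.57. In the authors' deposited table the fold change of Abca1 was -11.2, where its RPKM was 4.80-fold lower, and Abca1 lies in the part of the genome where the deposited values are shifted.

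Abca1, Scd1 and Lpl are targets of the liver X receptor, a nuclear receptor for oxidised cholesterol, and a lower activity of this receptor in KO is a hypothesis. Of 9 other tested targets 6 had negative log2 fold changes, with a median of -0.40 and a camera p from limma of 0.0147 (p = 0.204 with an estimated correlation). These include Srebf1 and Acaca, members of the fixed fatty acid list whose result had been seen. Without them 4 of 7 were negative, with a median of -0.032 and a camera p from limma of 0.212, so the negative median of the 9 rests on genes already seen, and the data cannot tell whether the receptor's targets differ as a set.

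Areg, Cd44, Thbs1, Anxa5 and Sprr1a include genes known from a transitional state of alveolar cells after injury, and a shift of KO cells towards such a state is a hypothesis. Of 17 other tested genes of that state 15 had positive log2 fold changes, with a median of 0.59 and a camera p from limma of 2.72e-05, which met the prediction. Among them were Ereg (1.36 ± 0.467 RPKM in KO, 0.0805 ± 0.0175 in WT), Anxa1 (90.5 ± 31.6 and 45.4 ± 4.32) and Clu (13 ± 4.78 and 5.14 ± 2.88). Ereg was below 1 RPKM in both WT libraries, so the filter kept it only because of its level in KO. Sfn differed mainly in KO 35, at 2.54 and 7.20 RPKM in KO 27 and KO 35 against 2.49 and 2.15 in WT 27 and WT 35. Itgb6 was alike in KO 27 and KO 35, at 11.5 and 12.1 RPKM against 9.19 and 7.45 in WT 27 and WT 35. The median of this set with 1 library left out was not computed. The set did not pass camera with an estimated correlation (p = 0.254) or fry (p = 0.162), so the data cannot tell. Camera at the preset correlation also called 3 fixed lists with the groups of the titles and 5 with the split by sex (the sex-linked list not counted). Real differences by heading number or by sex were not excluded there, so these calls do not settle the question. The 4 tested immune cell markers, of 12, had higher RPKM in both KO libraries as well, though Tyrobp and Cd52 passed the filter only through the KO libraries.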
